A study of Mus musculus with 2 samples.

How the data were processed

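MicroRNA sequencing was carried out on 2 libraries of mouse hindbrain at embryonic day 15.5, each from a separate pool of embryos of both sexes. Per the labels, the strain was B6NCrl, replicate 1 pooled the hindbrains of 78 embryos and replicate 2 those of 62, and the size range of the RNA was below 30 (the unit is not given). The series holds 1 group and no treatment, other tissue or other age. The only comparison that the design gives is that of the 2 biological replicates, and no test between conditions exists.

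The authors deposited 1 table of read counts per library, on build mm10 per the labels and with the GENCODE M4 annotation per the notes deposited with the tables. The aligner, the read trimming and the counting tool are not given in the sources used here. Each deposited table holds 1973 gene rows, and 4 further rows with totals of reads that were not assigned to a gene: unmapped, placed at several loci, outside any gene, and ambiguous. Each gene row holds 3 deposited counts, for both strands together, for the gene's own strand and for the opposite strand. The first equalled the sum of the other 2 in every gene row. The rows and columns have the layout of STAR's gene counts, in which a read placed at several loci is given to no gene. No label or note names that tool, so this reading is an inference from the layout. The rows that name no gene were left out of library sizes and tests. Of all reads, they held 34.8% ± 0.826 placed at several loci, 14.7% ± 1.48 unmapped and 2.76% ± 0.279 outside any gene (mean and SD, n = 2), and 0 ambiguous reads.

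Gene symbols and positions were taken from GENCODE M21, which uses the same build as mm10 (GRCm38), by gene identifier without its version. A symbol was found for 1894 of the 1973 identifiers, and the 79 without one held 8 reads in both libraries together. A gene row counts reads over the hairpin gene, so the 5p and 3p arms are not separated. Whether a gene lies in an exon or intron of another gene on its strand was taken from M21. The longest exact stretch that a hairpin shares with a microRNA gene elsewhere in the genome was found from the M21 transcript sequences, on either strand, with a minimum of 20 nt. No genome sequence was used, so copies outside annotated microRNA genes were not searched.

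The tables have no header line, so of the 2 columns that count a single strand, the one with the larger total was taken as the gene's own strand and used. Levels are given as CPM, the count scaled by the library's total on the genes' own strand, with the mean and SD over the 2 libraries (n = 2). The libraries were compared after TMM scaling in edgeR 4.0.16 (R 4.3.3), over the 426 genes with at least 10 reads in at least 1 library. For each gene the log2 ratio of replicate 2 over replicate 1 has an exact 95% interval and an exact two-sided conditional binomial p, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. This test compares these 2 libraries and covers counting error only, since there is 1 library on each side. Reads carry no molecular identifiers here and are not independent molecules, so intervals and floors understate the true error. The biological coefficient of variation came from an edgeR model with an intercept alone. Shares of reads have exact Clopper-Pearson 95% intervals. Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used.

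The 18 lists of microRNA genes were fixed before the data were examined, with 183 symbols, of which 164 genes were found in the tables. A symbol not found directly was looked up among RefSeq synonyms. The lists cover brain-enriched genes, the let-7 family, the miR-125 and miR-99/100 family, the miR-17-92 and paralogous clusters, the Hox clusters, the imprinted Dlk1-Dio3 region, the miR-183 sensory cluster (Mir183, Mir96 and Mir182) and oligodendrocytes. They also cover other cells a dissection could hold: choroid plexus and ciliated epithelium, other epithelium, endothelium, erythroid cells, leukocytes, mesenchyme and smooth muscle, striated muscle, liver, pancreas and endocrine tissue, and pluripotent stem cells. A list with at least 3 tested genes was compared between the libraries by the median log2 ratio of its genes, with 0.5 read added to each count. That median was set against 10000 random lists of the same size drawn from the same deciles of expression. The percentile describes these libraries and is not a p-value, the less so for lists whose genes lie in 1 cluster, such as miR-183, Dlk1-Dio3 and most of the pancreas list. The genes named in the text were fixed by rule: the 25 with the highest mean CPM, the 3 highest members of each list, the 10 with the largest ratio past the threshold with at least 100 reads in a library, and the 5 with the largest share of reads on the opposite strand, with ties ordered by the number of reads. Other members are named to complete a list.

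The alternatives were DESeq2 1.42.0 size factors or total counts in place of TMM, other count minimums, the count of both strands, an edgeR exact test with a fixed coefficient of variation, another pseudocount, the most abundant gene left out, and each library alone. The binomial test was checked on simulated counts for the same 426 genes, of which 200 were changed. These counts held counting error only, which is what the test assumes. The binomial test recovered 66% of genes changed 1.5-fold and 81% of those changed 2-fold, and called 1.33% of the unchanged genes. The intervals held the true ratio for 94.8% of genes. The libraries themselves varied more, with a biological coefficient of variation of 10.5%, so these rates are not error rates for the real comparison. A simulated coefficient of variation of 10% was estimated as 10.1% ± 0.678 (SD over 20 draws).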

Results

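The microRNA content of the mouse hindbrain, which forms the cerebellum, pons and medulla, was profiled at embryonic day 15.5 in 2 biological replicates. Each was a pool of hindbrains, from 78 embryos in replicate 1 and 62 in replicate 2. Replicate 1 held 8327917 reads and replicate 2 held 10507754. Of these, 48.4% (95% exact interval 48.3 to 48.4) were assigned to microRNA genes in replicate 1 and 47.0% (47.0 to 47.1) in replicate 2. Reads placed at several loci, which are listed apart from the genes, made up 35.4% and 34.2%. Unmapped reads made up 13.7% and 15.8%, and reads outside the annotated microRNA genes 2.56% and 2.96%. On the genes' own strand lay 3937840 reads in replicate 1 and 4839647 in replicate 2, and these were used for all levels. A count of 0 allows up to 3 reads, or 0.762 CPM in replicate 1 and 0.62 CPM in replicate 2, by counting error only. This limit does not hold for genes that share sequence with another locus, whose reads can be placed at several loci.

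A few genes held most of the reads that were assigned to a gene. Reads placed at several loci are listed apart from the genes. Genes that share sequence with another locus may therefore stand too low in this order and in the list shares below. Mir99a (ENSMUSG00000065530.1), in an intron of its host transcript Mir99ahg on chromosome 16 from 77598936 to 77599000, held 16.6% ± 0.779 of the gene reads (SD, n = 2). It was followed by Mir10a (ENSMUSG00000065519.1; chromosome 11, 96317165 to 96317274), a Hox cluster microRNA, at 7.13% ± 1.49. Mirlet7g (ENSMUSG00000065440.1), in an intron of Wdr82 on chromosome 9, held 6.12% ± 0.244, and Mirlet7i (chromosome 10) held 4.64% ± 0.202. Mir10b, annotated in an intron of Hoxd3 on chromosome 2 from 74726070 to 74726137, held 3.94% ± 1.30. Mir335, in an intron of the imprinted gene Mest, held 3.93% ± 0.399, Mir100 held 3.90% ± 0.214 and Mir487b 3.46% ± 0.166. The 10 most abundant genes held 54.5% ± 0.491 of the gene reads and the 25 most abundant 72.9% ± 0.0960. In each library 63 genes held 90% of the gene reads. Of the 1973 genes, 372 had at least 10 reads in both libraries and 1252 had none in either.

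**Figure D1:**
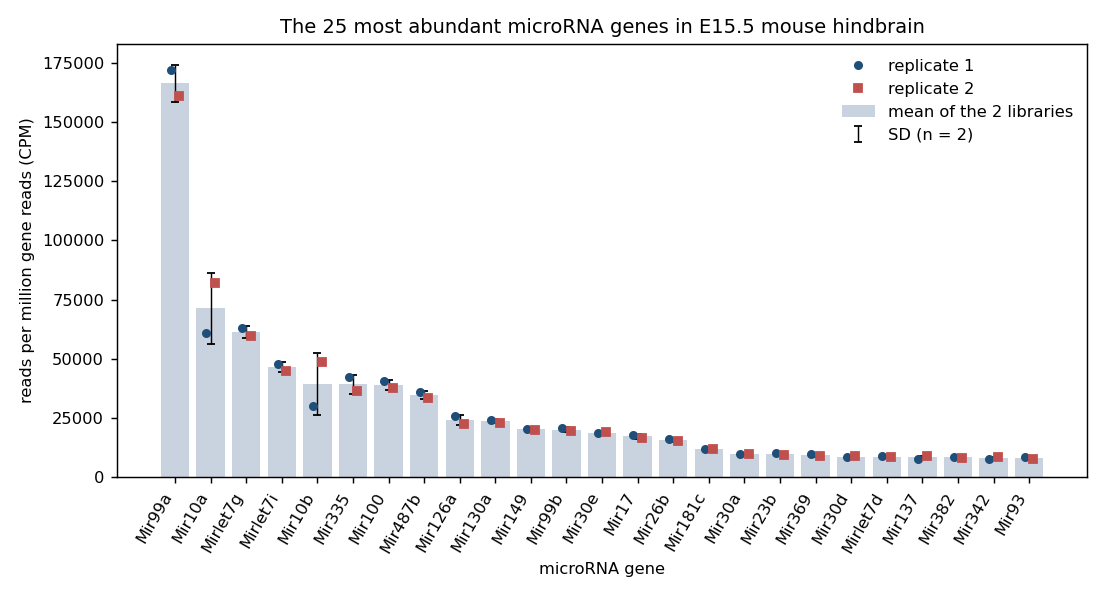
CPM (vertical axis, linear from 0) for the 25 most abundant microRNA genes, with bars for the mean of the 2 libraries, error bars for the SD (n = 2), and a point for each library. Mir99a stands first at 166329 CPM, and the 2 libraries lie farthest apart relative to the mean for Mir10a and Mir10b, both higher in replicate 2.

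The order of the leading genes was compared with the spread between the pools. In reads, Mir99a exceeded Mirlet7g 2.73-fold in replicate 1 and 2.70-fold in replicate 2, far more than the spread of either gene between the pools. That spread cannot show a bias between genes that both libraries share, so the order is one of reads and not of molecules. Mir10a and Mirlet7g were not separable: their ratio was 0.965 in replicate 1 and 1.38 in replicate 2. With 2 libraries, an exact permutation test that treats the values of 2 genes as unpaired cannot give a two-sided p below 0.33. Pairing them by library allows fewer arrangements still, so no p-value is given for such orders.

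The developmental-timing and growth families were all present at high levels. The list that joins the miR-125 and miR-99/100 genes held 23.6% ± 1.03 of the gene reads, carried by Mir99a, Mir100 and Mir99b (2.01% ± 0.112). Its miR-125 genes held far less: 0.742% for Mir125a, 0.182% for Mir125b-1 and 0.181% for Mir125b-2. Mir125b-1 and Mir125b-2 share 24 nt with each other, so reads of either can be placed at several loci. Their levels and the list's share are uncertain for that reason. The let-7 family, which accumulates as progenitors differentiate, held 13.3% ± 0.481, with 10 of its 10 measured genes above 10 reads in both libraries. Among reads assigned to a single gene its leading members were Mirlet7g, Mirlet7i and Mirlet7d (0.873% ± 0.0252). Of the 10 genes 5 share at least 20 nt with another locus, and Mirlet7e and Mirlet7f-1 were not analysed here, so the order within the family is uncertain. The family's share leaves out Mirlet7e and Mirlet7f-1. The miR-17-92 and paralogous clusters, associated with proliferating progenitors, held 4.16% ± 0.202, led by Mir17 (17206 ± 1095 CPM), Mir93 (8148 ± 794 CPM, in an exon of Mcm7) and Mir20a (5779 ± 484 CPM). The imprinted Dlk1-Dio3 region on chromosome 12, which carries a large neuronally expressed microRNA cluster, held 9.43% ± 0.293. Of its 41 measured genes 39 had at least 10 reads in both libraries, led by Mir487b (34649 ± 1658 CPM), Mir369 (9258 ± 528 CPM) and Mir382 (8354 ± 422 CPM). Mir409, Mir376a, Mir380 and Mir299a, annotated in this region, have no count of their own here. On the strand opposite to Gm24321, where Mir409 is annotated, lay 19498 and 23262 reads. At Gm25252, opposite to Mir376a, lay 15021 and 17909 such reads, and the region's share leaves these out.

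The brain-enriched list held 4.91% ± 0.0672 of the gene reads over 26 measured genes. Mir149 was its highest member at 20337 ± 297 CPM, followed by Mir137 (8360 ± 637 CPM) and Mir135b (7686 ± 299 CPM). The neuronal Mir124a genes had between 6 and 21 reads each, and Mir9-2 had 6 and 17. Mir9-3, which shares 26 nt with another locus, had 1991 and 3125 reads (576 ± 99.1 CPM). Of the 26 genes, 17 share a stretch of at least 20 nt with another microRNA locus, so a read from that stretch can be placed at several loci. The levels of such genes are uncertain for that reason. The oligodendrocyte list held 0.266% ± 0.00783, mostly from Mir219a-2 (2118 ± 109 CPM), with Mir338 at 344 ± 21.9 CPM and Mir219a-1 at 203 ± 8.40 CPM. Mir219a-2 and Mir219a-1 share 22 nt with another locus, and their levels are uncertain in the same way.

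MicroRNAs of other cell types and tissues were measured in the same libraries. Mir126a, the endothelial microRNA in Egfl7, held 2.42% ± 0.219. The mesenchymal and smooth muscle list held 0.627% ± 0.0502, almost all from Mir143 (5857 ± 448 CPM), with Mir214 at 224 ± 6.62 CPM and Mir199b at 98.9 ± 44.0 CPM. Of its 6 genes 3 share at least 20 nt with another locus, Mir199b among them, and their levels are uncertain. Choroid plexus and ciliated epithelium held 0.639% ± 0.110, from Mir449a (2854 ± 555 CPM), Mir204 (2168 ± 355 CPM) and Mir34c (1319 ± 178 CPM). The miR-183 sensory cluster held 0.696% ± 0.112, from Mir182 (3336 ± 369 CPM), Mir183 (2847 ± 602 CPM) and Mir96 (782 ± 151 CPM). The pancreas and endocrine list held 0.126% ± 0.00939, from Mir375 (675 ± 6.05 CPM), Mir217 (394 ± 72.2 CPM) and Mir216b (126 ± 15.5 CPM).

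Lower still were the pluripotent stem cell list at 0.0973% ± 0.00234, from Mir302a (372 ± 2.94 CPM), Mir302d (309 ± 8.74 CPM) and Mir302b (231 ± 19.1 CPM), and the epithelial list at 0.0609% ± 0.00616, led by Mir203 (494 ± 50.4 CPM), Mir429 (44.6 ± 7.38 CPM) and Mir205 (29.7 ± 5.44 CPM). Of the 6 leukocyte symbols 3 were found, and these genes held 0.0428% ± 0.00718, from Mir223 (191 ± 45.9 CPM), Mir155 (159 ± 18.3 CPM) and Mir150 (77.9 ± 7.61 CPM). Mir142, also on the leukocyte list, has no count of its own here. On the strand opposite to Mir142b, where Mir142 is annotated, lay 1255 and 1133 reads, more than the 879 and 766 of Mir223, and the leukocyte share leaves them out. Liver genes held 0.0176% ± 0.00168, from Mir194-2 (69.5 ± 3.66 CPM), Mir192 (59.4 ± 5.38 CPM) and Mir122 (46.3 ± 15.2 CPM). Of the 4 erythroid symbols 2 were found, and these genes held 0.0149% ± 0.00344, from Mir451a (119 ± 19.7 CPM) and Mir144 (30.5 ± 14.7 CPM). The leukocyte and erythroid shares are therefore those of part of each list. Striated muscle genes held 0.00538% ± 0.00110, with Mir206 at 25.3 ± 2.70 CPM, Mir208b at 21.1 ± 12.6 CPM and Mir499 at 4.35 ± 0.310 CPM. Mir1a-1, Mir133a-1, Mir133a-2 and Mir133b had no read in either library. Of the 8 muscle genes measured, 4 share at least 20 nt with another locus and could lose reads in the same way.

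**Figure D2:**
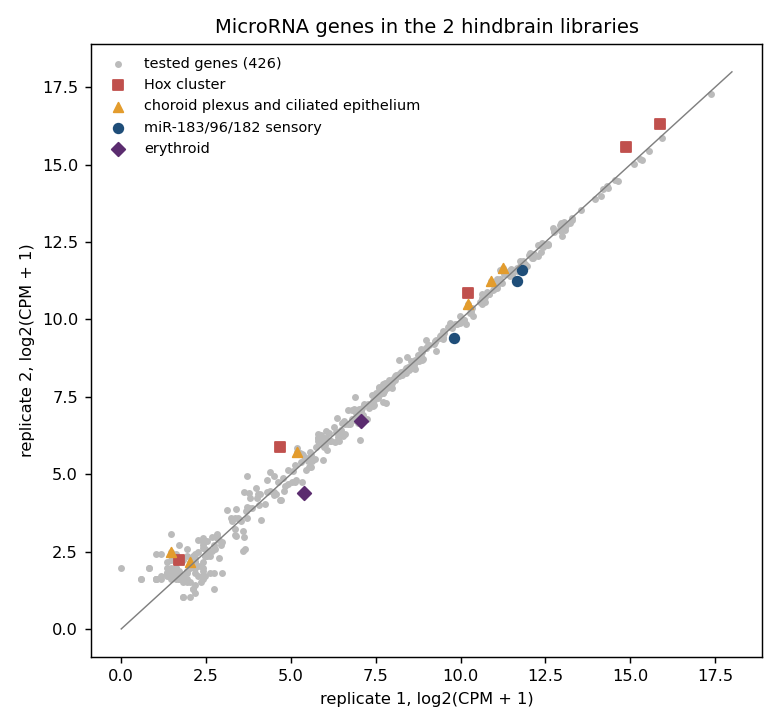
Level of each of the 426 tested genes in replicate 1 (horizontal axis) and replicate 2 (vertical axis), both as log2(CPM + 1), with 4 fixed lists marked and the line of equal levels. The points follow the line with r = 0.995. The Hox cluster genes lie above the line and the miR-183 cluster genes below it.

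The 2 pools were compared to measure how far biological replicates of this tissue differ. Across the 426 genes, log2(CPM + 1) had a Pearson r of 0.995 (bootstrap interval over genes 0.994 to 0.996) and a Spearman rho of 0.988 (0.980 to 0.992). Genes are not independent replicates. The biological coefficient of variation was 10.5% (bootstrap interval over genes 8.67 to 12.02, 100 draws). That interval rests on these 2 pools alone and does not cover how the value would vary with other pools. Over the 208 genes with a mean of at least 100 CPM, the log2 ratio had an SD of 0.18. By the exact binomial test 152 of 426 genes differed beyond counting error at an adjusted p of 0.05, 65 of them higher in replicate 2 and 87 higher in replicate 1. Most of these differences were small: 23 genes differed by at least 1.5-fold, 15 of them higher in replicate 2 and 8 higher in replicate 1. Of the 25 most abundant genes, 24 differed by less than 1.5-fold, and Mir10b was the exception. When genes were allowed a coefficient of variation of 0.1, close to the one estimated, edgeR's exact test called 6 genes. These were Mir196b, Mir208b, Mir193a and Mir6988, higher in replicate 2, and Mir199b and Mir144, lower. Mir193a and Mir6988 fall outside the naming rule and were chosen after their values were seen. Mir6988 had 0 reads in replicate 1 and 14 in replicate 2, which is 3.75-fold higher if replicate 1 is set at the floor of 3 reads. That value leaves out the counting error of the 14 reads and is not a lower bound. With a coefficient of variation of 0.2, edgeR's exact test called 0 genes, with 12 at an unadjusted p under 0.05.

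Hox cluster microRNAs, which lie among the genes that pattern the head-to-tail axis, were higher in replicate 2. The list held 9.21% of the gene reads in replicate 1 and 13.2% in replicate 2, a ratio of 1.44. Of its 5 tested genes 4 were higher past the binomial threshold, both over all genes tested and adjusted over the list alone, and 3 of them by at least 1.5-fold. Mir196b, annotated in an exon of Hoxa9 on chromosome 6, had 96 and 281 reads, a log2 ratio of 1.24 (95% exact interval 0.90 to 1.58, counting error only). The log2 ratio was 0.67 (0.66 to 0.68) for Mir10b, 0.60 (0.55 to 0.65) for Mir615 in an intron of Hoxc5, and 0.41 (0.41 to 0.42) for Mir10a. Mir196a-2 had 9 and 18 reads and was not called, and Mir196a-1 had 1 read in each library and was not tested. The list's median log2 ratio of 0.65 lay at percentile 99.9 of the random lists. With a coefficient of variation of 0.1 assumed for every gene, edgeR's exact test still called Mir196b of the Hox genes, and with 0.2 it did not. With 1 library on each side, a larger variation of Mir196b itself cannot be told apart from a difference between the pools.

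Choroid plexus and ciliated epithelium genes were also higher in replicate 2, with 4 of 6 tested genes past the threshold over all genes and 5 adjusted over the list alone. The median log2 ratio was 0.35, at percentile 98.9, and at 95.5 when genes with 1 read were admitted. Mir449a, in an intron of Cdc20b, had a log2 ratio of 0.38 (0.35 to 0.42), Mir204 in an intron of Trpm3 0.32 (0.28 to 0.36), and Mir34c 0.26 (0.21 to 0.31). The intervals and the threshold cover counting error only. At a coefficient of variation of 0.1, edgeR's exact test called no gene of the choroid plexus, pancreas or brain-enriched lists. In the pancreas and endocrine list (median 0.30, percentile 99.7), 3 of 4 genes were higher in replicate 2, and these lie in 1 cluster on chromosome 11 from 28746191 to 28763835: Mir217 at 0.36, Mir216a at 0.38 and Mir216b at 0.23. Mir375, the list's gene from another locus, was at -0.04 and did not pass. The brain-enriched list had a small median of 0.11 at percentile 99.8, with 8 genes higher and 3 lower of 26 (8 and 4 adjusted over the list alone). Of the 26 genes, 17 share at least 20 nt with another locus, so reads placed at several loci may be missing from their ratios. Genes that share sequence with each other, such as Mir128-1 and Mir128-2, are not independent members.

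The miR-183 sensory cluster was lower in replicate 2, with 3 of 3 genes past the threshold and a median log2 ratio of -0.41 at percentile 0.05. The log2 ratio was -0.45 (-0.49 to -0.42) for Mir183, -0.41 (-0.48 to -0.34) for Mir96 and -0.24 (-0.28 to -0.21) for Mir182. These 3 genes form 1 cluster, and the threshold covers counting error only. None of them was among the genes that edgeR's exact test called at a coefficient of variation of 0.1, nor was any Dlk1-Dio3 gene. The Dlk1-Dio3 list had a median of -0.08 at percentile 2.02, with 17 genes lower and 2 higher in replicate 2 of 39 tested (18 and 3 adjusted over the list alone). Some blood and mesenchymal genes were lower, while the leukocyte and mesenchymal list medians lay inside the central 95% of random lists. Both measured erythroid genes passed the threshold, Mir144 at -1.05 (-1.42 to -0.67) and Mir451a at -0.36 (-0.54 to -0.18). Of 3 leukocyte genes 2 passed, Mir223 at -0.51 (-0.65 to -0.37) and Mir155 at -0.25 (-0.41 to -0.10), with a list median of -0.25 at percentile 5.46, and Mir150 at -0.22 (-0.44 to 0.00) did not. Of 5 mesenchymal genes 3 passed, Mir199b at -0.96 (-1.16 to -0.75), Mir199a-2 at -1.22 (-2.01 to -0.45) and Mir143 at -0.17 (-0.20 to -0.15), with a list median of -0.17 at percentile 6.42. Mir214 at -0.08 and Mir145a at 0.01 did not pass. The erythroid list, with 2 genes, was not set against random lists. Endothelial Mir126a was lower by a log2 ratio of -0.20 (-0.21 to -0.19).

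**Figure D3:**
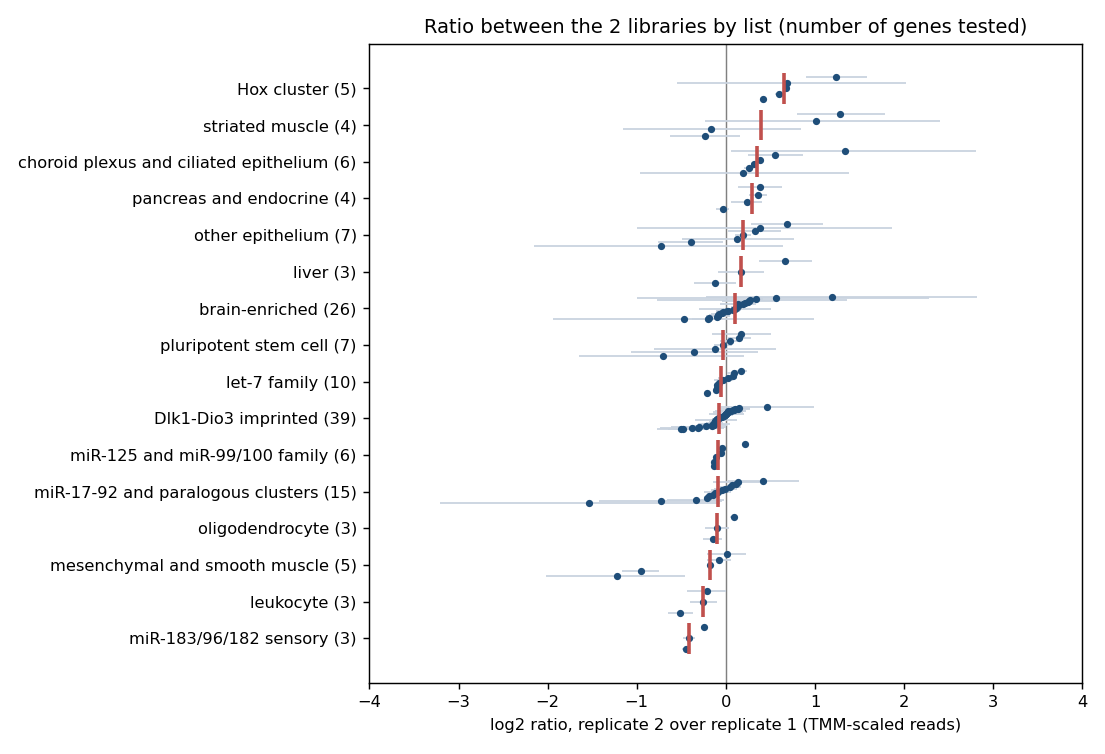
Log2 ratio of replicate 2 over replicate 1 (horizontal axis) for each tested gene of the 16 lists with at least 3 such genes (1 line per list, with the number tested). Points are genes, horizontal lines their exact 95% intervals (counting error only) and red ticks the list medians, which run from -0.41 for the miR-183 cluster to 0.65 for the Hox clusters.

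The medians of the remaining lists lay inside the central 95% of random lists. The let-7 median was -0.05 (percentile 45.8), with 2 genes higher and 5 lower of 10 (3 and 5 adjusted over the list alone). The miR-125 and miR-99/100 median was -0.08 (39.2), with 1 gene higher and 3 lower of 6 (1 and 4), and that of the miR-17-92 and paralogous clusters was -0.09 (14.96), with 2 higher and 4 lower of 15 (2 and 4). The oligodendrocyte median was -0.10 (16.2), with 1 gene higher and 1 lower of 3. The other epithelial median was 0.19 (81.1), and of 7 genes 2 were higher, Mir200c by a log2 ratio of 0.69 (0.29 to 1.09) and Mir203 by 0.19 (0.10 to 0.28). The liver median was 0.17 (69.7), and of 3 genes 1 was higher, Mir122 at 0.66 (0.37 to 0.97). The striated muscle median was 0.39 (88.1), larger than that of the choroid plexus list but on 4 genes of few reads, of which 1 was higher, Mir208b, in an intron of Myh7, with 48 and 145 reads and a log2 ratio of 1.28 (0.80 to 1.78). The pluripotency median was -0.03 (38.0), and none of its 7 tested genes passed the binomial test, Mir302b being closest with an adjusted p of 0.0545 by the exact binomial test. Outside the lists, the rule for large ratios named Mir3067 at 0.61 (0.14 to 1.09) and Mir450b at -0.62 (-0.97 to -0.27). In all, 6 of the 16 lists compared lay outside the central 95% of random lists. Random lists take genes from separate loci, and genes of 1 cluster can move together, so how many lists would do so by chance is not known.

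The libraries kept the strand of the RNA. Reads on the genes' own strand made up 97.8% of gene reads in replicate 1 (95% exact interval 97.8 to 97.8) and 97.9% in replicate 2 (97.9 to 97.9). In 8 genes with at least 100 reads every read lay on the opposite strand. The 5 of them with the most such reads were Gm25927 on chromosome 17, with 23571 and 28825 opposite reads, Gm24321 (19498 and 23262) and Gm25252 (15021 and 17909) on chromosome 12, Gm24083 on chromosome 9 (11408 and 14128), and Gm25301 on chromosome 18 (11886 and 10507). Outside the 32 genes that overlap a microRNA gene annotated on the other strand, opposite reads numbered 117 in replicate 1 and 159 in replicate 2.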

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

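The tests of copies and of lost strand information were chosen after the results were seen. The test of overlapping genes was written before its result was seen.

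Reads on the strand opposite to the annotated gene made up most of the reads at 11 genes with at least 100 reads, above the 3 reads that a count of 0 allows. Over both libraries there were 52396 such reads at Gm25927, 42760 at Gm24321, 32930 at Gm25252, 25536 at Gm24083, 22393 at Gm25301, 5173 at Gm25750, 3931 at Mir299b, 3635 at Mir497b, 2388 at Mir142b, 874 at Gm24111 and 236 at Gm25641, together 99.8% of all opposite reads. A loss of strand information is argued against, since the other 301 genes of that depth had a median opposite share of 0%. An overlap with a microRNA gene on the other strand was tested by annotated position, and the sequences of the reads were not examined. All 11 genes, 100%, overlap a microRNA gene that GENCODE M21 places on the other strand, against 5.32% of the other genes, and the overlapped genes have no row in the tables used here. A candidate explanation is that these reads come from those genes: Mirlet7e at Gm25927, Mir409 at Gm24321, Mir376a at Gm25252, Mir191 at Gm24083, Mir378a at Gm25301, Mir142 at Mir142b and Mir9-1 at Gm25641. It does not cover Mir203, outside these 11 genes, with 41 and 48 opposite reads (2.00% of its reads) and no microRNA gene annotated on the other strand.

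Reads placed at several loci numbered 2947397 in replicate 1 and 3596192 in replicate 2, or 73.0 per 100 gene reads on average, and are not given by gene. The 3 Mir124a genes, whose microRNA is known as abundant in neurons, had 6 to 21 reads each. A candidate explanation is that reads shared between copies were not assigned, since the 3 hairpins share a stretch of 32 nt. The test could not decide this, since it compares different genes, whose levels vary whether or not they share sequence. The 49 listed genes that share at least 20 nt differed from the other 115 by -0.60 on the log2 scale, with medians of 203 and 309 CPM (two-sided permutation test, p = 0.376). With a minimum of 22 nt, chosen after the data were seen, the difference was -0.39 (permutation p = 0.501). Low expression of miR-124 cannot be told apart from this loss, because the tables do not give the reads placed at several loci by gene.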

How the results depend on the processing

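Depth limits what can be said of genes under about 10 reads. With no filter beyond 1 count, Spearman's rho was 0.943, and with at least 100 counts r and rho were 0.996 and 0.996. With log2(CPM + 10), r was 0.998. Counts of 10 or more in both libraries were seen for 372 genes, and of at least 1 count for 602. The 152 genes that differed beyond counting error became 6 and 0 when edgeR's exact test allowed a coefficient of variation of 0.1 and 0.2, and the 23 genes with at least 1.5-fold became 6 and 0, since that variation is added by construction. At 0.2, 12 genes had an unadjusted p under 0.05. With at least 100 counts, 11 genes differed 1.5-fold, as fewer genes were tested. The other scalings and filters and the count of both strands gave between 136 and 162 genes, and with no filter 71 were higher in replicate 2 and 65 lower. Scaling moved the median of all tested genes by less than 0.1 on the log2 scale. Of the lists, choroid plexus fell inside the random lists with no filter (median log2 ratio 0.35, percentile 95.5), and the pluripotency median of -0.03 reversed to 0.12 with at least 100 counts, inside the random lists in both cases. The cause was not tested. Hox, brain-enriched, miR-183 cluster, Dlk1-Dio3 and pancreas lists kept their direction and side under the 5 alternatives that were run. Among these, DESeq2 size factors and total counts shift every ratio alike, so the side could not change under them. The other count minimums and the count of both strands could have changed it. Of uniquely placed reads 94.5% lay on gene rows, against 47.7% of all reads. Without genes that overlap one on the other strand, 99.997% of reads lay on the gene's strand. With Mir99a left out, the first gene held 8.67%, the first 10 47.9% and the first 25 68.4%, and with both strands counted the last 2 were 53.4% and 71.3%. List shares with Mir99a left out were 5.88% for brain-enriched (4.80% with both strands), 16.0% for let-7, 8.42% for miR-125 and miR-99/100, 4.99% for miR-17-92 and paralogs, 11.3% for Dlk1-Dio3, 0.836% for miR-183 cluster, 0.32% for oligodendrocyte, 0.766% for choroid plexus, 0.073% for other epithelium, 2.90% for endothelial, 0.051% for leukocyte, 0.752% for mesenchymal, 0.021% for liver, 0.151% for pancreas and 0.117% for pluripotent genes. With 1 library left out, each share was the other library's own value: for Mir99a 16.1% without replicate 1 and 17.2% without replicate 2, and for the Hox list 13.2% without replicate 1 and 9.21% without replicate 2. The comparison of the libraries cannot be run with 1 left out. No paired analysis was possible because the series has 1 group.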

Other observations

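In the closing tests below, those of scaling, counting error, genes of like GC content and caudal tissue were chosen after the results were seen, and that of a linear GC trend was written before.

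Htr2c, the serotonin receptor gene expressed in choroid plexus, carries several microRNA genes in its introns, which were looked at after the choroid plexus list had been seen. Mir1298 had 9052 reads in replicate 1 and 14854 in replicate 2, a log2 ratio of 0.40 (95% exact interval 0.36 to 0.44), at a mean of 2684 CPM. Mir448 had 1138 and 1972 reads (0.48, 0.37 to 0.59) and Mir1264 had 753 and 1083 (0.21, 0.07 to 0.35). These 3 were higher in replicate 2 past the exact binomial threshold, which covers counting error only. Mir764 (27 and 29 reads) and Mir1912 (19 and 20 reads) were not. None of these genes was among those that edgeR's exact test called at a coefficient of variation of 0.1. The log2 ratio of Mir449a, Mir204 and Mir34c, from 3 other loci, lay between 0.26 and 0.38.

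Hox cluster microRNAs were higher in replicate 2 by a median log2 ratio of 0.65, with exact intervals above 0 for 4 of 5 tested members, which restates the binomial test. Scaling is argued against, since a common factor moves all genes alike and so cannot give the 0.66 by which the list's median lay above that of the other tested genes. Removing a linear trend on hairpin GC content moved the median only to 0.64, so the percentile after it (99.9) tests nothing. GC bias shared by genes of like hairpin GC content is argued against. The list lay at percentile 99.8 of random lists drawn within 5 points of each member's hairpin GC content. The GC content of the reads themselves was not measured, so a bias by read sequence remains open. A hypothesis is that the replicate 2 pool may hold more caudal tissue. It would give a higher ratio for Mir196 genes, beside Hox9 and Hox10, than for Mir10a, Mir10b and Mir615, beside Hox4 and Hox5. The medians differed by 0.36 in that direction, but the split was made after the ratios were seen and rests on Mir196b. Mir196a-2, 1 of 2 Mir196 genes, was at 0.69 with an interval that includes 0 (-0.54 to 2.02), beside 0.67 for Mir10b. The difference is therefore no test of the hypothesis. With 1 pool on each side, a difference in dissection, in embryo stage or in the pools themselves remains open.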
